A study of Homo sapiens with 6 samples.

How the data were processed

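RNA of LNCaP cells was measured on 6 Affymetrix Human Genome U219 arrays. Per the labels, cells were grown in F12 medium with fetal bovine serum, kept for 24 h with saline or 40 µM urolithin A, and extracted with an RNeasy kit, and biotin-labelled cRNA was made by an automated system. Groups and replicate numbers come from the sample titles, with 3 arrays in each of 2 groups. No batch, plate position or scan date was used here, so batches could not be examined. No arrays of a group held identical values.

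The deposited table holds log2 values of 49386 probe sets, made by the authors with RMA, per the submitters' processing notes, which give no version. RMA corrects background, quantile-normalizes the arrays and summarises each probe set on the log2 scale. In all 49386 probe sets the median of the 3 control arrays was exactly 0, which shows that the control median had been subtracted. The base of the logarithm is not stated. It was taken as 2 because RMA works on that scale, and values between -4.49 and 6.6 leave no room for base 10. The subtraction keeps differences between arrays and removes levels, so no value says whether a transcript was abundant or near background. The median of the deposited values was 0 in each control array and -0.0013, 0.0058 and 0.014 in urolithin A replicates 1, 2 and 3.

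Probe sets were named through the annotation table of the platform, whose symbols needed 0 updates against the gene identifiers of the reference table. One symbol was listed for 45253 probe sets, several symbols for 1327 and none for 2713, apart from 93 control probe sets. Only probe sets with a single symbol entered the gene-level fits. They cover 18239 genes, of which 11822 have more than 1 probe set. A gene's value on an array was the mean of its probe sets. The rule set before the data were examined took the probe set with the highest mean, and named the mean of the probe sets as the replacement if the values proved to be centred. No coordinates are given, because the sources used here name no genome build.

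Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, treatment as the only term, two-sided moderated test), with Benjamini-Hochberg adjustment over the 18239 genes and a threshold of 0.05. Fold sizes are 2 to the power of the size of the log2 change. Limma's camera compared each of 28 gene lists with all other genes, with a preset correlation between genes of 0.01 and adjustment over the 28 lists, and was repeated with a correlation estimated from the data. These lists were written before the data were examined, and 497 of their 536 entries had a named probe set. They cover androgen response, p53, the cell cycle, stress pathways, metabolism, autophagy and markers of cell types. A further 10 lists were written after the data had been seen and are used only in the closing observations.

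Named genes followed a rule set before the data were examined. It took the 10 highest and 10 lowest changes among genes that passed and whose urolithin A arrays all lay outside the control range, and 8 genes fixed in advance, of which 2 are not analysed here. From each list that camera called it took the 4 members with the smallest p, and from each other list up to 2 members that passed. A further condition of the rule on signal level could not be applied to centred values. The rule gave 87 genes. Other genes named in the text were chosen after their values were seen or are given as the only members of a small count.

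Data were simulated with limma's moderated variances for these arrays and with 200 genes changed. The gene-level fit recovered 34% of genes changed 1.25-fold, 96% of those changed 1.5-fold and 100% of those changed 2-fold. In the deposited data 1854 genes passed, so these shares may not carry over. In that simulation 20 of 18039 unchanged genes were called. Over 20 repeats the unchanged genes made up 6.22% of the calls on average, somewhat more than the threshold of 0.05 allows. Camera called 0 of 27 random lists there. The simulated genes varied independently, so this result cannot show how often camera calls lists of correlated genes.

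Alternatives set in advance were a block for the replicate number, every probe set tested alone, median centring, a trended and robust prior, no moderation, array weights, a threshold of 0.01, a fold minimum of 1.5, each array left out, and for the lists an estimated correlation and limma's fry. Alternatives added after the data were seen were the median of a gene's probe sets, probe sets without names that mark shared sequence, scaling on hybridization controls, and fits without the arrays with raised HLA-DRA.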

Results

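LNCaP is an established human line of androgen-responsive prostate adenocarcinoma cells. Urolithin A is a compound that gut bacteria make from ellagitannins and ellagic acid of the diet. Total RNA of LNCaP cells was hybridised to Affymetrix Human Genome U219 arrays, with 3 arrays of control cells and 3 of cells kept with 40 µM urolithin A for 24 h. The sample titles call the controls untreated, while the treatment protocol names saline; the solvent of urolithin A is not stated. The question was which transcripts differ after this exposure. Every deposited value is a log2 value relative to the median of the 3 control arrays, so differences between arrays can be read, and levels cannot. The number of arrays limits the precision. The labels do not say that the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

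After urolithin A, 23 of 28 measured genes that androgen induces were lower, 18 of 28 targets of p53 were higher, and 16 of 34 genes of DNA replication and 11 of 33 of mitosis were lower. As lists, these 4 passed limma's camera with its preset correlation and not with an estimated one (adjusted p = 0.0876, 0.0876, 0.308 and 0.333 with an estimated correlation). Of 18239 genes, 1854 changed at an adjusted p under 0.05, with 885 higher and 969 lower. The changes were mostly small, with a median size of 1.34-fold among the changed genes. A rise of at least 2-fold was seen for 19 of them and a fall of at least 2-fold for 74. The urolithin A arrays lay wholly outside the range of the controls in 29.3% of all genes, where chance gives 10%.

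The highest rise among genes that passed was that of TP53I3, an oxidoreductase gene that p53 induces, by 2.07 on the log2 scale (SE 0.18, adjusted p = 0.00046). TFF1 had a larger mean change of 2.48 but did not pass (adjusted p = 0.155), as its urolithin A arrays ranged from -0.29 to 4.39. CDKN1A, the inhibitor of cyclin-dependent kinases also called p21, rose 2.60-fold (log2 change 1.38, SE 0.10, adjusted p = 0.000315). Also among the 10 highest were FCGBP, which codes for a mucin-like secreted protein, at 2.86-fold, and the dynein light chain gene DYNLT2B at 2.61-fold. The only probe set listed for the small nucleolar RNA SNORD72 rose 2.56-fold and was among them too. Which transcript of that locus it detects was not examined. CCDC92 rose 2.54-fold, C6orf52 2.47-fold, and both the proteoglycan gene SDC4 (syndecan-4) and the gluconokinase gene IDNK 2.22-fold. The alpha-tubulin gene TUBA1A had a log2 change of 1.44 (SE 0.35, adjusted p = 0.034), and its call ended without any single array other than urolithin A replicate 3, at adjusted p up to 0.103. Control replicate 3 lay at -0.98 for TUBA1A, and without that array its log2 change was 1.08.

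The deepest fall among the tested genes was that of LAMA1, the laminin alpha 1 chain of basement membranes, by 11.8-fold (log2 change -3.56, SE 0.12, adjusted p = 1.19e-05). SNAI2, a repressor of epithelial genes, fell 4.84-fold, although its 3 control arrays ranged from -0.65 to 0.53. The proteoglycan gene SPOCK1 fell 4.75-fold, the phospholipase gene PLA1A 4.27-fold, the membrane protein gene TM4SF1 4.10-fold and the pseudogene GRM5P1 3.82-fold. For TM4SF1, 3 of 4 probe sets fell, and the remaining probe set had a log2 change of 0.12. The alpha-tubulin genes TUBA3E and TUBA3D, at 4.33-fold and 3.69-fold lower, are close in sequence, so their probe sets are not independent. The kallikrein gene KLK2 and the serine protease gene TMPRSS2, both induced by androgen, were also among the 10 lowest. All 10 of these falls held without each single array. Outside the gene-level fits, a probe set listed with several symbols fell further, by 20.2-fold (log2 change -4.33, SE 0.12, adjusted p = 3.33e-06).

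**Figure D1:**
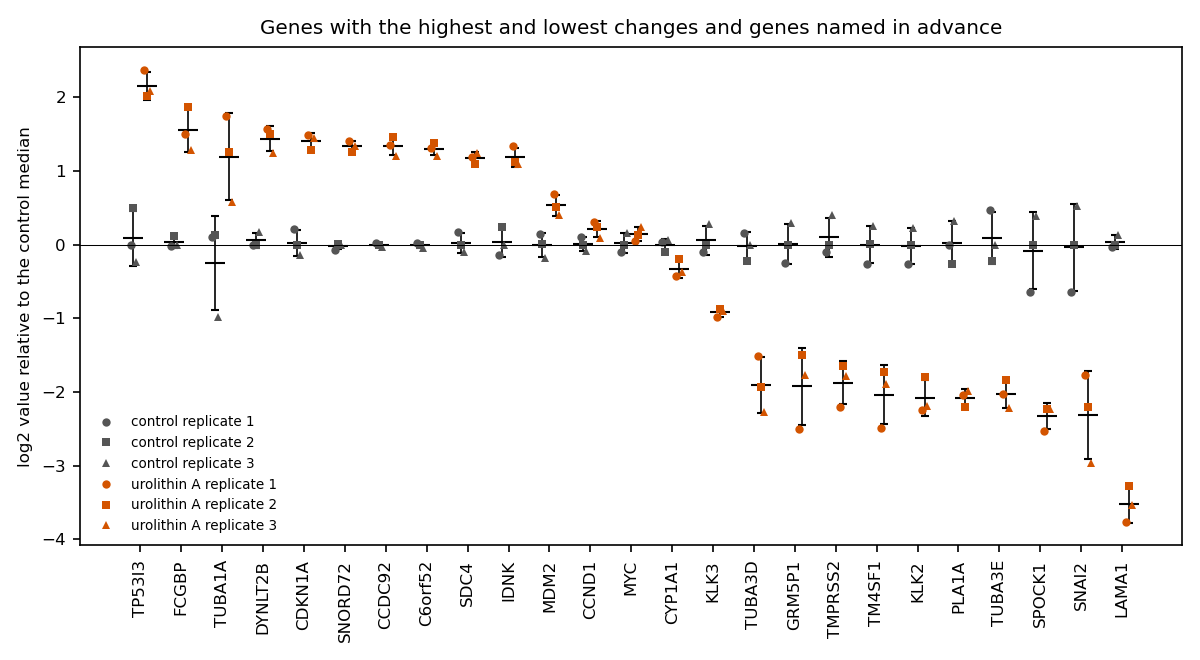
Log2 values relative to the control median (vertical axis) in each of the 3 control arrays (grey) and 3 urolithin A arrays (orange), for the genes with the 10 highest and 10 lowest changes and for genes fixed in advance, with the marker shape giving the replicate number and the bars the mean ± SD of 3 arrays. TP53I3 stands highest at a log2 change of 2.07 and LAMA1 lowest at -3.56, while the arrays of both groups overlap for MYC and CCND1.

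Androgen-induced genes formed the list with the deepest fall. Of 28 measured members, 23 fell, none rose and 5 did not pass, and the list's median log2 change was -1.11. KLK2 fell 4.19-fold (log2 change -2.07, SE 0.15, adjusted p = 0.000315), TMPRSS2 3.94-fold, the transcription elongation cofactor gene EAF2 3.55-fold and the synaptic scaffold gene HOMER2 3.01-fold. KLK3, which codes for prostate-specific antigen, fell 1.97-fold (log2 change -0.98, SE 0.10, adjusted p = 0.00101), and each of its 7 probe sets fell. MAF, a transcription factor gene, fell 2.16-fold, while 1 of its 4 probe sets had a log2 change of 0.05. Adjusted over the list alone, 24 members were lower. Limma's camera placed the list below all other genes (adjusted p = 6.6e-26 with the preset correlation). The list did not pass with an estimated correlation (adjusted p = 0.0876 with an estimated correlation).

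Genes known to be held down by androgen moved the other way. Of 7 measured members, 4 rose and 3 did not pass, with a median log2 change of 0.87, and 5 were higher adjusted over the list alone. Risen were CAMK2N1, an inhibitor of a calmodulin-dependent kinase, at 2.07-fold and the glucuronidation enzymes UGT2B17 at 2.10-fold, UGT2B15 at 1.93-fold and UGT2B10 at 1.83-fold. The 3 UGT2B genes are close copies whose probe sets may share signal, and all 3 are also in the list of conjugation and efflux genes. The call of UGT2B10 (adjusted p = 0.0248) ended without control replicate 2 (adjusted p = 0.0773) and without control replicate 3 (adjusted p = 0.0771). The list passed camera at adjusted p = 5.3e-05, and not with an estimated correlation (adjusted p = 0.0876 with an estimated correlation).

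Targets of p53, the tumour suppressor that arrests or kills damaged cells, were raised. Of 28 measured members, 18 rose, 1 fell and 9 did not pass, and the median log2 change was 0.54. Beside TP53I3 and CDKN1A, the nucleotide excision repair gene DDB2 rose 2.12-fold (log2 change 1.08, SE 0.07, adjusted p = 0.000222) and SPATA18, which acts in mitochondrial quality control, 1.77-fold. The pro-apoptotic genes BBC3 and BAX rose 1.80-fold and 1.46-fold. MDM2, the ubiquitin ligase that p53 itself induces, rose 1.46-fold (adjusted p = 0.0143), with 6 of its 11 probe sets passing, all of them higher. The member that fell was the kinase gene PLK2, at a log2 change of -0.33. Adjusted over the list alone, 21 members were higher and 1 lower. Camera gave an adjusted p of 1.48e-14 with the preset correlation. The call was lost with an estimated correlation (adjusted p = 0.0876 with an estimated correlation).

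Part of the cell cycle genes were lower. Of 34 measured genes of the G1/S transition and DNA replication, 16 fell, none rose and 18 did not pass, with a median log2 change of -0.39. The replication fork genes CDC45, POLE2, GINS2 and GINS1 fell 1.81-fold, 1.80-fold, 1.73-fold and 1.57-fold. Of 33 genes of G2/M and mitosis, 11 fell and 22 did not pass, with a median of -0.32. The mitotic kinesin gene KIF20A fell by 0.58 on the log2 scale and the proliferation marker MKI67 by 0.40. CCNA2, the cyclin A2 gene, fell 1.47-fold and the kinesin gene CENPE 1.35-fold. The call of CCNA2 ended without control replicate 1 (adjusted p = 0.0551) or control replicate 2 (adjusted p = 0.056), and that of CENPE without control replicate 1 (adjusted p = 0.0588) or urolithin A replicate 1 (adjusted p = 0.0561). Adjusted over the list alone, 23 and 22 members were lower. Camera gave adjusted p = 1.48e-14 and 2.4e-12. Both lists failed with an estimated correlation (adjusted p = 0.308 and adjusted p = 0.333 with an estimated correlation), and the mitotic list also with fry (adjusted p = 0.0543). The array medians of the replication list were 0.02, 0.03 and -0.17 in control replicates 1, 2 and 3 and -0.41, -0.30 and -0.53 in urolithin A replicates 1, 2 and 3. Control replicate 3 and urolithin A replicate 3, the lowest of each group, also had low 18S ribosomal RNA, at -0.45 and -0.48.

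Among 16 measured inhibitors of cyclin-dependent kinases, G1 cyclins and their partners, 3 rose, 1 fell and 12 did not pass (4 higher and 2 lower adjusted over the list alone), and camera did not call the list (adjusted p = 0.359), whereas fry did (adjusted p = 0.038). CDK2, the kinase that drives entry into S phase, fell 1.49-fold (adjusted p = 0.00361). CCND1, the cyclin D1 gene, had a log2 change of 0.21 that did not pass (adjusted p = 0.156), and its groups overlapped.

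Genes of ribosome biogenesis and MYC targets were lower, whereas MYC itself did not pass, at a log2 change of 0.12 (SE 0.09, adjusted p = 0.465). Of 20 measured members, 6 fell and 14 did not pass, with a median of -0.22, and 12 were lower adjusted over the list alone. The ribosome assembly genes MRTO4 and WDR43 fell 1.71-fold and 1.53-fold, NOLC1 fell 1.27-fold and RRP9 1.35-fold. Of the 3 probe sets of NOLC1, 1 had a log2 change of 0.07. The call of RRP9 ended without control replicate 1, control replicate 3 or urolithin A replicate 1, at adjusted p up to 0.0715. The camera call (adjusted p = 4.87e-08) was lost with an estimated correlation (adjusted p = 0.0876 with an estimated correlation).

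Genes of sterol synthesis were lower by small amounts. Of 18 measured members of the cholesterol list, 6 fell and 12 did not pass, with a median of -0.21 (1 higher and 6 lower adjusted over the list alone). EBP, a sterol isomerase, fell 1.43-fold and HMGCS1, an early enzyme of the pathway, 1.33-fold, while ACAT2 fell 1.27-fold and CYP51A1 1.23-fold. The calls of ACAT2 and CYP51A1 each ended in 5 of the 6 fits without a single array, at adjusted p up to 0.0649 and 0.0737, and that of HMGCS1 without control replicate 3 (adjusted p = 0.0505) or urolithin A replicate 1 (adjusted p = 0.0565). The exceptions were urolithin A replicate 2 for ACAT2 and urolithin A replicate 3 for CYP51A1. The camera call at adjusted p = 0.00119 was lost with an estimated correlation (adjusted p = 0.352 with an estimated correlation) and with fry (adjusted p = 0.0501).

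In the list of hypoxia and glycolysis genes, 4 of 18 measured members fell and 14 did not pass, with a median of -0.12 (6 lower adjusted over the list alone). These 4 were NDRG1, which androgen also induces, at 2.01-fold, the kinase gene PDK1, which restrains pyruvate oxidation, at 1.88-fold, the hexokinase gene HK2 at 1.45-fold and ANKRD37 at 1.27-fold. The call of HK2 ended without control replicate 1, control replicate 3 or urolithin A replicate 2, at adjusted p up to 0.0579. For HK2 and for ANKRD37, 1 of 2 probe sets passed on its own. Camera called the list (adjusted p = 0.0188), but not with an estimated correlation (adjusted p = 0.182 with an estimated correlation), nor when probe sets open to cross-hybridization were left out (adjusted p = 0.0964), nor without urolithin A replicate 3 and control replicate 1 (adjusted p = 0.0724), nor with urolithin A replicate 1 against control replicates 2 and 3 (adjusted p = 0.141). Of 10 measured genes of fatty acid synthesis, 3 fell and 7 did not pass (1 higher and 3 lower adjusted over the list alone), and camera did not call the list (adjusted p = 0.277). It did so only with urolithin A replicate 1 against control replicates 2 and 3, at a median of -0.34 (adjusted p = 0.00735, against up to 0.793 under the other settings). The elongase gene ELOVL5 fell 1.91-fold. ACLY, the citrate lyase gene, fell 1.27-fold, a call kept only without control replicate 1 or urolithin A replicate 3 among the fits that lack an array, with adjusted p up to 0.0827 in the others.

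Antioxidant genes of the NRF2 pathway were higher. Of 17 measured members, 6 rose and 11 did not pass, with a median of 0.22, and 8 were higher adjusted over the list alone. The quinone reductase gene NQO1 rose 1.72-fold, the heme oxygenase gene HMOX1 1.67-fold, SQSTM1, the autophagy receptor p62, 1.43-fold and GCLM, a subunit of the enzyme that starts glutathione synthesis, 1.41-fold. Camera gave an adjusted p of 2.62e-05, which was lost with an estimated correlation (adjusted p = 0.182 with an estimated correlation). Of 23 genes of mitophagy, autophagy and the lysosome, 7 rose, 1 fell and 15 did not pass, with a median of 0.19 (10 higher and 1 lower adjusted over the list alone). The mitophagy kinase gene PINK1 rose 1.54-fold (log2 change 0.62, SE 0.07, adjusted p = 0.0011) and MAP1LC3B, which marks autophagosomes, 1.40-fold. LAMP2, a lysosomal membrane protein gene, rose 1.47-fold as the mean of 9 probe sets, of which 5 rose and 1 fell. Camera gave an adjusted p of 2.61e-05, not kept with an estimated correlation (adjusted p = 0.0876 with an estimated correlation).

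The list of metallothioneins, which bind zinc and other metals, and zinc export was higher. Of 8 measured members, 7 metallothioneins and a single exporter, 3 rose and 5 did not pass, with a median of 0.32, and 4 were higher adjusted over the list alone. MT1F rose 1.80-fold, MT2A 1.73-fold and the zinc exporter gene SLC30A1 1.32-fold, although neither of the 2 probe sets of SLC30A1 passed on its own. MT1G had a log2 change of 0.62 and did not pass (adjusted p = 0.0931), but passed with the replicate number as a block (adjusted p = 0.00751) and with scaling on the hybridization controls (adjusted p = 0.00348), against up to 0.39 under the other settings. The call of MT2A ended without control replicate 1 (adjusted p = 0.0572) or control replicate 2 (adjusted p = 0.0601). Camera gave an adjusted p of 0.00125, lost with an estimated correlation (adjusted p = 0.333 with an estimated correlation) and with fry (adjusted p = 0.0501). Of 16 chaperone and degradation genes of the endoplasmic reticulum, 2 rose and 14 did not pass, with a median of 0.16 (3 higher adjusted over the list alone). DNAJB9, a co-chaperone gene, rose 1.68-fold. HSPA5, the main chaperone of that compartment, rose 1.29-fold, and 1 of its 6 probe sets passed on its own. Its call was lost in 5 of the 6 fits without an array (all but that without urolithin A replicate 1, adjusted p up to 0.0997). DNAJC3 and HSP90B1 had log2 changes of 0.24 and 0.18 that did not pass, although HSP90B1 passed without moderation (adjusted p = 0.0438) and DNAJC3 in a single probe set (adjusted p = 0.041). This list's camera call (adjusted p = 0.0188) was lost without control replicate 2 (adjusted p = 0.0992), without urolithin A replicate 2 (adjusted p = 0.0912), with urolithin A replicate 1 against control replicates 2 and 3 (adjusted p = 0.329), with fry (adjusted p = 0.0761) and with an estimated correlation (adjusted p = 0.596 with an estimated correlation).

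**Figure D2:**
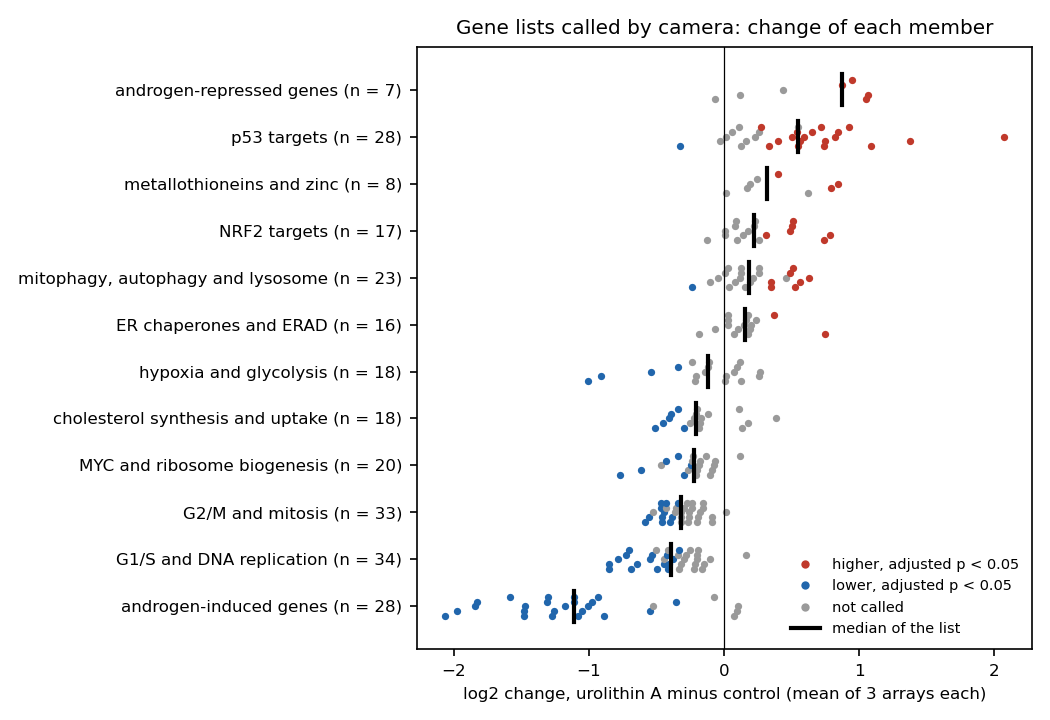
Log2 change of each measured member (horizontal axis, urolithin A minus control, means of 3 arrays each) of the 12 gene lists that camera called with its preset correlation, ordered by median. Red points rose and blue points fell at an adjusted p under 0.05 over all genes, grey points did not pass, and black bars mark the list medians, from -1.11 for androgen-induced genes to 0.87 for androgen-repressed genes.

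In all, camera called 12 of the 28 lists with its preset correlation, 6 higher and 6 lower. With an estimated correlation it called 0 lists, with 7 at an unadjusted p under 0.05. The estimated correlation was 0.0037 for the androgen-repressed list and -0.0187 for the hypoxia list, both below the preset 0.01. A higher correlation therefore does not account for the loss of these calls. In the other called lists it was higher, from 0.0124 for autophagy to 0.578 for mitosis. The estimates rest on 4 residual degrees of freedom. Limma's fry, which asks only whether a list's genes move on balance in a single direction, called 11 lists, of which 8 were also called by camera. Fry did not call 4 of camera's lists, those of mitosis, cholesterol, metallothioneins and the endoplasmic reticulum, and called 3 that camera did not, those of kinase inhibitors and G1 cyclins, apoptosis and luminal genes. The preset-correlation test also called between 2 and 10 lists in the other 9 ways of dividing the 6 arrays into 3 and 3, each of which sets 2 arrays of a group against 1.

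Camera did not call the remaining lists with the values as deposited and all 6 arrays. Of 24 regulators of apoptosis, 3 rose and 21 did not pass (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.107, fry adjusted p = 0.0312), the risen being BBC3, BAX and BID. Among 25 genes of the integrated stress response, SESN2, an inhibitor of growth signalling that p53 also induces, rose 1.64-fold and the other 24 did not pass (1 higher adjusted over the list alone, camera adjusted p = 0.359). This list passed only without control replicate 3 (adjusted p = 0.0173). Of 8 targets of the aryl hydrocarbon receptor, NQO1 rose, CYP1A1 fell and 6 did not pass (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.951). CYP1A1, the cytochrome whose induction marks this receptor's activity, had a log2 change of -0.32 (SE 0.08, adjusted p = 0.0453), and its call ended in 5 of the 6 fits without an array, all but that without urolithin A replicate 2, at adjusted p up to 0.134. Of 33 genes of oxidative phosphorylation, UQCRB rose 1.26-fold, SDHD fell 1.19-fold and 31 did not pass (none adjusted over the list alone, camera adjusted p = 0.932). The call of SDHD ended without each single array, at adjusted p from 0.0636 to 0.133, and that of UQCRB without control replicate 1 or 3 or urolithin A replicate 1 or 2, at adjusted p up to 0.101. Of 15 conjugation and efflux genes, 3 rose and 3 fell (4 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.617). The efflux pump gene ABCC4, which androgen also induces, fell 2.42-fold, against the rise of UGT2B15.

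Little moved in the other stress and signalling lists. In 19 interferon response genes, RIGI, a sensor of viral RNA, rose 1.23-fold, a call that ended without each single array other than control replicate 2, at adjusted p up to 0.0878 (1 higher adjusted over the list alone, camera adjusted p = 0.953). In 12 heat shock genes, HSPA1A rose 1.48-fold and HSPE1 fell 1.19-fold (the same counts adjusted over the list alone, camera adjusted p = 0.706). Without control replicate 1 HSPA1A stood at adjusted p = 0.0501, and the call of HSPE1 ended without each single array, at adjusted p from 0.0607 to 0.13. In 10 estrogen-induced genes, GREB1 fell 1.37-fold (1 lower adjusted over the list alone, camera adjusted p = 0.617). Its call held only without control replicate 2 or urolithin A replicate 1 and otherwise ended, at adjusted p up to 0.0961. The estrogen list was called as higher when the arrays were scaled on their hybridization controls (adjusted p = 0.00363, against up to 0.826 under the other settings). Among 16 immediate early genes, limma called 0, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.617).

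Camera called none of the lists of cell markers with the values as deposited. The hybridization controls lay at -0.004, -0.264 and 0.159 in urolithin A replicates 1, 2 and 3, and between -0.0489 and 0.0327 in the control arrays. Scaling on them therefore moves the urolithin A arrays apart for all genes. Scaled in this way, the arrays gave a call for the luminal list (adjusted p = 0.000419, median -0.0015). The basal list was called too (adjusted p = 0.000421, median 0.038), and both lists were called as lower. Under camera's other settings neither passed, at adjusted p up to 0.856 and 0.753, while fry called the luminal list (adjusted p = 0.034). Of 13 luminal prostate genes, 1 rose, 2 fell and 10 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.425). The channel gene TRPM8, which is also in the androgen-induced list, fell 2.39-fold, and SPDEF, a luminal transcription factor gene, fell 2.17-fold. For TRPM8, 1 of 3 probe sets fell and another stood at a log2 change of 0.0023. Of 15 basal and mesenchymal markers, 1 rose, 3 fell and 11 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.321). The transcription factor gene TWIST1 fell 2.31-fold and FN1, the fibronectin gene, 1.72-fold, beside SNAI2, while the member that rose was VIM, at a log2 change of 0.57. INSM1 rose 1.18-fold in the list of 10 neuroendocrine markers (1 higher adjusted over the list alone, camera adjusted p = 0.735), a call that ended without each single array, at adjusted p from 0.0811 to 0.135. Limma called 0 of 11 fibroblast markers (camera adjusted p = 0.953) and 0 of 10 leukocyte and endothelial markers (camera adjusted p = 0.617), with 0 of either at an unadjusted p under 0.05. The sign of the median differed from that of the mean or the test for the lists of aryl hydrocarbon receptor targets, oxidative phosphorylation, interferon response, basal, neuroendocrine and fibroblast genes.

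Some genes differed more between arrays of the same group than between the groups. A few genes of lymphocytes, some of them of HLA class II, stood higher in urolithin A replicates 2 and 3 than in replicate 1. Of 37 B lymphocyte markers, 0, 3 and 7 exceeded the control median by more than 2-fold in urolithin A replicates 1, 2 and 3, with list medians of -0.05, 0.07 and 0.17, and 1 did so in control replicate 1. HLA-DRA lay at -0.02, 1.17 and 3.09 in urolithin A replicates 1, 2 and 3, and at 1.01 in control replicate 1. LAPTM5 lay at -0.08, 0.99 and 1.97 and CXCR4 at -0.18, 1.09 and 1.76 in the same 3 arrays. Other HLA class II genes differed among themselves. In these arrays HLA-DPA1 lay at -0.17, 0.20 and 1.43, HLA-DPB1 at 0.03, 0.25 and 0.73, HLA-DRB1 at 0.14, 0.13 and 1.74 and HLA-DQA1 at 0.04, 0.04 and 0.31, while HLA-DMA lay at -0.46, -0.28 and -0.26 and HLA-DMB at -0.10, -0.21 and -0.04. Of 16 T lymphocyte markers, 0 exceeded 2-fold in any array. HBB, the beta-globin gene, stood at 2.32 in urolithin A replicate 3 alone. The trefoil factor gene TFF1, a member of the estrogen-induced list, lay at 4.39, 3.14 and -0.29, and the keratin gene KRT19 at -0.06, -0.96 and -1.80. HLA-DRA, LAPTM5, CXCR4, HBB, TFF1 and KRT19 did not pass (adjusted p from 0.117 for KRT19 to 0.466 for HBB), and these 6, like the other HLA genes, were chosen after their values were seen. The array medians of urolithin A replicates 1, 2 and 3 were -1.05, -1.08 and -1.22 for the androgen-induced list, 0.64, 0.48 and 0.44 for the p53 list and -0.33, -0.14 and -0.43 for the mitotic list. Without urolithin A replicate 3 and control replicate 1, the arrays of each group with the highest HLA-DRA, 705 genes changed, and with urolithin A replicate 1 alone against control replicates 2 and 3, 48 genes did.

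**Figure D3:**
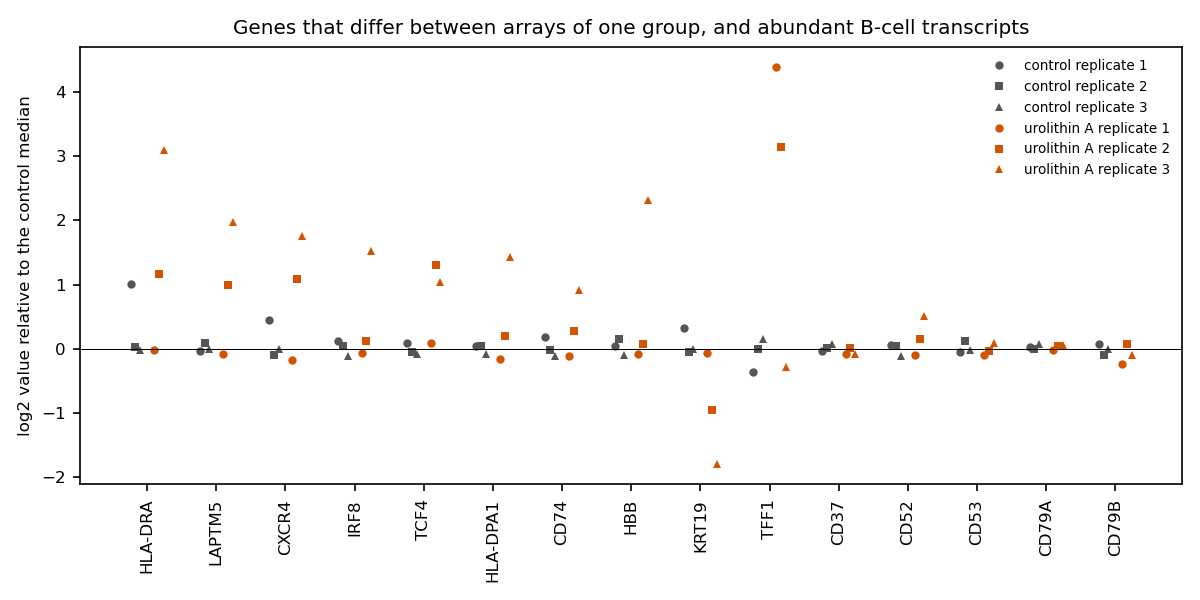
Log2 values relative to the control median (vertical axis) in each control (grey) and urolithin A (orange) array, with the marker shape giving the replicate number, for genes that stand apart in single arrays and, at the right, for 5 transcripts abundant in B cells. HLA-DRA reaches 3.09 in urolithin A replicate 3 and stays at -0.02 in replicate 1, while CD37, CD53, CD79A and CD79B lie between -0.24 and 0.12 in all 6 arrays and CD52 reaches 0.15 and 0.50 in urolithin A replicates 2 and 3.

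The number of changed genes depended on the arrays used. It lay between 1063 and 1309 when a single array was left out, and the lowest value came without control replicate 2. It was 560 without moderation of the variances and 646 when the arrays were scaled on their hybridization controls.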

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

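The tests of chance, of cross-hybridizing probe sets and of array scaling were set before their results were seen. The scaling itself was chosen after the data had been seen. The tests on lymphocyte genes, mislabelling, luminal cells and RNA degradation were set after their results were seen. Probe sets outside the gene-level comparison also changed. Among 1327 probe sets listed with several symbols, limma called 91, with 42 higher and 49 lower, and among 2713 probe sets with no listed gene it called 226, with 109 higher and 117 lower. These shares, 6.86% and 8.33%, stand beside 8.46% of the probe sets with a single symbol. They were singled out because they lie outside the data used for the report's comparison. The largest change among all probe sets was a fall of 20.2-fold in a probe set listed with several symbols (log2 change -4.33, SE 0.12, adjusted p = 3.33e-06).

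Whether chance explains the counts cannot be settled by regrouping, because 6 arrays divide into 3 and 3 in only 10 ways. In 1 of the 10, the real division, 1854 genes changed, and the highest number in any other was 0 (limma, with 414 to 770 genes at an unadjusted p under 0.05). For the gene lists the real division gave 12 called lists, again the most in 1 of 10, while another division gave 10. Each other division sets 2 arrays of a group against 1, so part of the difference between the groups stays in it, and differences between single arrays enter as well.

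The fall of the androgen-induced list, with a median log2 change of -1.11, was weighed against 3 technical or cellular explanations. A lower share of luminal cells would lower other luminal markers by about as much, but the 11 luminal genes outside the list had a median of 0.0548 (95% bootstrap interval over genes -0.21 to 0.16). LNCaP is a single cell line, so no other cell type was known whose share could change, and this comparison weighs little. Degraded RNA would lower the signal from the 5′ ends, but the contrast of 5′ against 3′ control probe sets of ACTB and GAPDH changed by -0.0687 (SE 0.06). Scaling on the hybridization controls left the median at -1.08. This scaling subtracts the same value from all genes of an array, and the median of all genes went from 0.0101 to 0.0441. Such a shift could not remove a fall particular to the list, so this comparison cannot weigh the explanation. As a hypothesis, the fall may belong to the response to urolithin A, with the unstated solvent and any shared handling of the treated arrays left open and untested.

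A few lymphocyte genes were raised in single arrays, with HLA-DRA at -0.02, 1.17 and 3.09 in urolithin A replicates 1, 2 and 3 and at 1.01 in control replicate 1. A mislabelled replicate 3 is argued against by its androgen-induced median of -1.22 (interval -1.40 to -0.93). RNA of lymphocytes in replicates 2 and 3 may be the source: in replicate 3 CD37, CD52, CD53, CD79A and CD79B had a median of 0.0599, while CD52 alone lay at 0.50, CD74 at 0.91, CD48 at 0.87 and IGHM at 0.68. With no levels in the deposited values, the background of these probe sets is unknown, and this source stays open, as does a response to urolithin A that differs between cultures, which the median of 37 B lymphocyte markers, at -0.049, 0.07 and 0.17 in urolithin A replicates 1, 2 and 3, was too low to weigh. Against such a response as the whole cause, untreated control replicate 1 resembled urolithin A replicate 3 across these genes, which are not independent (r = 0.755, where replicates 2 and 1 had 0.692 and 0.117), but without HLA-DRA, CXCR4 and HLA-DRB1 its r was 0.353, against 0.59 and 0.121, and a single control array does not exclude it.

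In 52 genes, out of 755 with more than 1 called probe set, some probe sets rose and others fell. LAMP2 and ATG5, both of the autophagy list, are among them. The real division of the arrays was the only 1 of 10 with any such gene. No probe set was called in any other division, so the highest number there, 0, was fixed in advance and cannot weigh chance. The 52 genes were also not set against the false calls that a threshold of 0.05 allows. Names that mark shared sequence were no more frequent among the called probe sets of these genes (27.9%) than among other called ones (32.7%). The odds ratio was 0.798 (95% interval 0.52 to 1.19, Fisher's exact test, two-sided, p = 0.292). This argues only against an excess of probe sets so named. Cross-hybridization of probe sets without such names, the only ones called for ARIH1, SENP5 and TMEM248, was not tested. Transcript variants that respond differently may be present, a hypothesis that was not tested.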

How the results depend on the processing

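The hybridization-control scaling, the gene median, the unique probe sets and the fits of 2 against 2 and 1 against 2 arrays were chosen after seeing the data. The highest-mean probe set, the filter on dim genes and cyclic loess were not run, because the centred values hold no levels, which also keeps signal over background unknown. Leaving out an array gave 1063 to 1309 changed genes, 482 to 628 higher and 581 to 681 lower, and 11 to 13 called lists; with fewer arrays fewer genes pass. Changed, higher and lower genes numbered 560, 262 and 298 without moderation, 646, 334 and 312 with hybridization-control scaling, 705, 320 and 385 with 2 against 2 and 48, 15 and 33 with 1 against 2, where the lone array is assumed to vary like the controls. They numbered 4144, 1977 and 2167 over all probe sets, where more features are tested, 642, 272 and 370 at an adjusted p under 0.01 and 449, 179 and 270 with a fold minimum of 1.5. A trended, robust prior gave 574 higher genes. Apart from the fits that test more or fewer features or arrays or ask for more, the cause was not tested. Camera called 0 lists with an estimated correlation and 9 to 15 under the other settings. The replicate numbers were not taken to pair the arrays. The labels do not say that these numbers mark a shared day or batch. Over all genes, r between the deviations of same-numbered arrays was 0.0782, 0.0225 and 0.196. Replicates 1 and 3 correlated best with their own number and replicate 2 did not. These values do not exclude pairing, since genes such as FOS and TSC22D3 differed by replicate number in both groups. The array medians of the replication, mitosis and metallothionein lists also ranked the replicates alike in both groups. Those of the androgen-induced list, for example, did not. If the arrays are paired, the main fit counts variation shared by same-numbered arrays as error. With the replicate block 1863 genes changed, 1586 of them among the 1854, and 12 lists were called.

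Of 82 named genes that passed, 62 passed in all 6 fits without an array and 20 lost the call in at least 1, with no change of sign. The call was lost for 5 with the replicate block, 20 with hybridization-control scaling, 26 with 2 against 2, 61 with 1 against 2 and 40 without moderation. Of the probe sets of named genes tested alone, 156 gave the same result as the gene and 50 kept the direction without the call. For example, 1 of 2 probe sets passed alone for ANKRD37, CYP51A1 and HSPA1A, 1 of 3 for GREB1 and 2 of 6 for MKI67. Single probe sets turned the direction for LAMP2 (-0.0671, -0.356 and -0.449), HSPE1 (0.0072), MAF (0.052), NOLC1 (0.0732), TM4SF1 (0.123) and TRPM8 (0.0023). The cause was not tested. MT1G gained the call with the block and with hybridization-control scaling, and HSP90B1 without moderation. Among lists camera did not call, hybridization-control scaling called the luminal, basal and estrogen lists, 1 against 2 the fatty acid list, the fit without control replicate 3 the integrated stress list, and fry the G1 cyclin, apoptosis and luminal lists. No list reversed.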

Other observations

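The gene groups in this part were chosen after the data had been seen, and their list tests are descriptions. Genes of the Fanconi pathway and homologous recombination were lower, with 8 of 22 measured members fallen, none risen and 14 not passing (14 lower adjusted over the list alone). RAD54B and FANCI fell 1.85-fold and 1.78-fold, and BRCA1 fell 1.33-fold. Camera gave an adjusted p of 1.2e-06 over the 10 added lists, not kept with an estimated correlation (adjusted p = 0.202 with an estimated correlation). In the 33 genes of mitochondrial ribosomes, 6 fell, 1 rose and 26 did not pass (camera adjusted p = 0.00229, and adjusted p = 0.253 with an estimated correlation). Of 15 genes of HLA class I and antigen processing, TAP1 rose 1.56-fold and HLA-E 1.55-fold and 13 did not pass (camera adjusted p = 0.0196, and adjusted p = 0.643 with an estimated correlation). The array medians of this list were 0.07, 0.20 and 0.27 in urolithin A replicates 1, 2 and 3, and HLA-B, which did not pass, lay at -0.02, 0.31 and 0.54, higher in the arrays with high HLA-DRA. TAP1 lay between 0.58 and 0.66 and HLA-E between 0.52 and 0.80 in these 3 arrays.

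In 3 gene families, members moved in opposite directions. UGT2B28 had a log2 change of -1.04 (adjusted p = 0.0479), against the rise of UGT2B15 and UGT2B17. Among 17 glutathione S-transferases, GSTA4 rose 1.95-fold, GSTO2 and GSTZ1 rose 1.30-fold and 1.32-fold, and GSTA2 fell by 0.68 on the log2 scale (camera adjusted p = 0.536). Among 17 alpha and beta tubulins, TUBA1A was higher and TUBA3D and TUBA3E were lower (camera adjusted p = 0.337). Of 18 genes of the vacuolar ATPase, ATP6V1E2 and ATP6AP1 rose and none fell (camera adjusted p = 0.3). TXNIP, a binding partner of thioredoxin, rose 1.87-fold.

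Of the added lists of blood cell markers, limma called 0 of 37 B lymphocyte genes, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.154). It called 0 of 16 T lymphocyte genes, with 1 at an unadjusted p under 0.05, and 0 of 9 red cell genes, also with 1 (camera adjusted p = 0.724 for both). MPO, a granulocyte enzyme gene, fell 1.31-fold in a list of 14 (camera adjusted p = 0.724). The probe sets for 18S ribosomal RNA lay at -0.45 in control replicate 3 and -0.48 in urolithin A replicate 3, at -0.22 in urolithin A replicate 2, and between 0.015 and 0.047 in the other 3 arrays. Some genes differed by replicate number in both groups. FOS lay at 0.97, -0.08 and -0.20 in control replicates 1, 2 and 3 and at 0.93, -0.04 and -0.19 in urolithin A replicates 1, 2 and 3, and TSC22D3 at -0.64, 0 and 0.78 and at -0.71, 0.17 and 0.98. DDIT4, a stress-induced inhibitor of growth signalling, lay at -0.32, 0 and 0.76 and at 0.36, 0.66 and 1.43. Its log2 change of 0.67 did not pass (SE 0.32, adjusted p = 0.242) but passed with the replicate block (SE 0.06, adjusted p = 0.00292). Control replicate 3 also stood apart for some genes, with FKBP5 at 0.52 and TMSB4X at -0.75 relative to the control median.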
